A study of Mus musculus with 9 samples.

How the data were processed

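RNA of murine leukaemia cells driven by the MLL-AF9 fusion was profiled in 9 libraries, 3 for a control hairpin and 3 for each of 2 short hairpin RNAs (shRNAs) against Syncrip, at day 4 after transduction. Per the labels' protocols, total RNA was reverse transcribed from an oligo-dT primer and the other cDNA strand was primed with random decamers, so polyadenylated RNA was the main template. Each primer carried a sequencing linker, so fragments lie between the primed A stretch and a random site and weigh the tail end of transcripts. Fragment strand, read length and molecular identifiers are not given in the sources used here.

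The deposited values are raw read counts per gene symbol, 1 table per library. The submitters' processing notes name STAR 2.3.0e and HTSeq 0.6.0 and the mouse build mm10. The annotation release, the strand setting and the treatment of reads with several positions are not given in the sources used here. Each table held 39179 entries for 38926 symbols. A group of 176 symbols stood in 429 entries, which were summed per symbol and held 0.275% of the counts. Entries for unassigned reads were looked for and not found. Because the strand setting is not given, reads of overlapping or antisense genes cannot be told apart, and close paralogs share or lose reads.

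Genes were filtered with filterByExpr by group, which kept 12663 genes and removed 0.0908% of the counts. Library sizes were scaled with TMM factors, and all 9 libraries entered 1 fit with the group as the only term (edgeR 4.0.16 in R 4.3.3). The common biological coefficient of variation was 0.165. Differences were tested with edgeR's quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were each hairpin against the control and the hairpins against each other. A gene counted for both hairpins when it passed with each and had the same sign. Levels are TMM-scaled counts over the scaled library size, in CPM, given as mean ± SD over 3 libraries, and log2 fold changes are given ± standard error.

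The design, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named 9 genes whatever their values, Syncrip, Hnrnpr, Msi2, Hoxa9, Meis1, Myc, Myb, Ikzf2 and Cdkn1a. To these came the 12 largest rises and falls with both hairpins, the 5 largest rises and falls of each comparison, and up to 2 rises and 2 falls per gene list (or, where no member was called with both hairpins, the 2 members with the highest mean). The first kinds needed a mean of at least 5 CPM and no overlap between the libraries compared, and skipped names of the forms Gm, LOC, BC or AK plus digits and names ending in Rik. Clone names were not among these forms, so RP24-312B12.1 stayed. Some genes that the rule picked are not described here. Of the list members so named, Ear6, Hemgn, Pmvk, Kdm3a, Becn1, Fn1, Snrpa, Ndufs1, Rpl4, Rps16, Rpl27, Psma5, Psmb2, Hist1h1c, mt-Nd1, Aldh1l2, Ctsl, Psap and H2-DMa lost or gained a call when some 1 library was left out, and they enter the text only in the counts of their lists. The lists numbered 36, of which 25 hold cell programmes, 8 markers of other cell types and 3 genes that follow library quality. They came from general knowledge, and 981 of their 1004 entries had a symbol in the tables. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists and both comparisons with the control. None of the camera calls made with the preset correlation held with the estimated one.

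Gene positions, transcript lengths and GC content came from GENCODE release M21 on GRCm38, the assembly of mm10, matched by symbol for 12019 genes (94.9%). The pipeline was tested on simulated counts for 12460 genes with the real library sizes. For shRNA-1 against control it recovered 20.4% of genes changed 1.5-fold, 57.4% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 9 false calls among 12270 unchanged genes. For shRNA-2 the values were 20.4%, 61.7% and 100%, with 12 false calls. Few genes were changed in this simulation, so its adjusted threshold was stricter than in the data, where far more genes were called. Recovery in the data was therefore not measured.

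The alternatives were DESeq2 size factors in edgeR, total counts without TMM, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, fits of only the 2 groups compared, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each library in turn. The filter was rerun whenever a library was left out, so the number of list members tested could change. After the data had been seen, further fits left out the ribosomal RNA genes or used the log2 share of ribosomal RNA as a covariate. Others took out the trend of each library with transcript length or GC content. A last fit left out shRNA-1 replicate 3 and shRNA-2 replicate 1, called the outlying libraries here. They were not the 2 libraries farthest from their group means. In the log2 ribosomal RNA share, shRNA-2 replicate 2 deviated from its group mean by 0.658 and shRNA-1 replicate 3 by 0.357. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The hairpin sequences are not given in the sources used here, so off-target matches were not searched.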

Results

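Cells of a murine acute myeloid leukaemia, driven by the fusion of the histone methyltransferase KMT2A (MLL) with AF9 and passaged through mice by serial transplantation, were transduced with a control hairpin or with 1 of 2 hairpins against Syncrip. SYNCRIP is an RNA-binding protein of the hnRNP family, and the title of the series ties it to the stem cell programme of the leukaemia. Polyadenylated RNA was sequenced at day 4 in 3 libraries per group. The series' design text describes every sample as transduced and processed on its own. The p-values therefore measure the spread between separately handled cultures of 1 leukaemia, and whether these came from separate mice is not given in the sources used here. The design text names a luciferase hairpin as the control and the sample labels name a scrambled one, and which was used is not given in the sources used here.

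The controls had 18268263, 13683660 and 19483923, the shRNA-1 libraries 9559638, 13416141 and 12180557, and the shRNA-2 libraries 15915940, 14953491 and 15038631 counts. Principal component 1, with 51.1% of the variance, set the shRNA-2 libraries apart from the other 6, and component 2, with 25.9%, set the shRNA-1 libraries apart from the controls. Counts under Gm26924, mt-Rnr1 and mt-Rnr2 were counted as ribosomal RNA, a sign of how much RNA without a long poly(A) tail entered a library. Gm26924 is read as ribosomal RNA from general knowledge only and was not found in the annotation used here, and the share and the fits with it rest on that reading. The share was 6.97% ± 1.92 in the controls, 15.4% ± 3.69 with shRNA-1 and 10.7% ± 4.84 with shRNA-2 (mean ± SD, n = 3 each). All 3 shRNA-1 libraries lay above all 3 controls, where chance gives 10% for either order. Gm26924 alone took 5.03% ± 1.82, 9.95% ± 2.04 and 7.69% ± 3.63, and the mitochondrial genes 1.94% ± 0.134, 5.41% ± 3.11 and 3.05% ± 1.45 (mean ± SD, n = 3 each).

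Syncrip, the targeted gene (chromosome 9, 88447009 to 88482574 on mm10), was lower with both hairpins and more so with shRNA-1. Its level was 227 ± 17.5 CPM in the controls, 17.8 ± 2.13 with shRNA-1 and 56.7 ± 9.05 with shRNA-2 (mean ± SD, n = 3 each). The control libraries lay between 207 and 241 CPM and the knockdown libraries between 15.9 and 63.2, in the order the labels give. The level was 12.8-fold lower with shRNA-1 (log2 fold change -3.68 ± 0.16) and 4.00-fold lower with shRNA-2 (-1.999 ± 0.15), with edgeR quasi-likelihood adjusted p = 3.79e-07 and 2.19e-06. The hairpins differed by -1.68 ± 0.15 (shRNA-1 minus shRNA-2, adjusted p = 9.67e-06 in the same test).

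**Figure D1:**
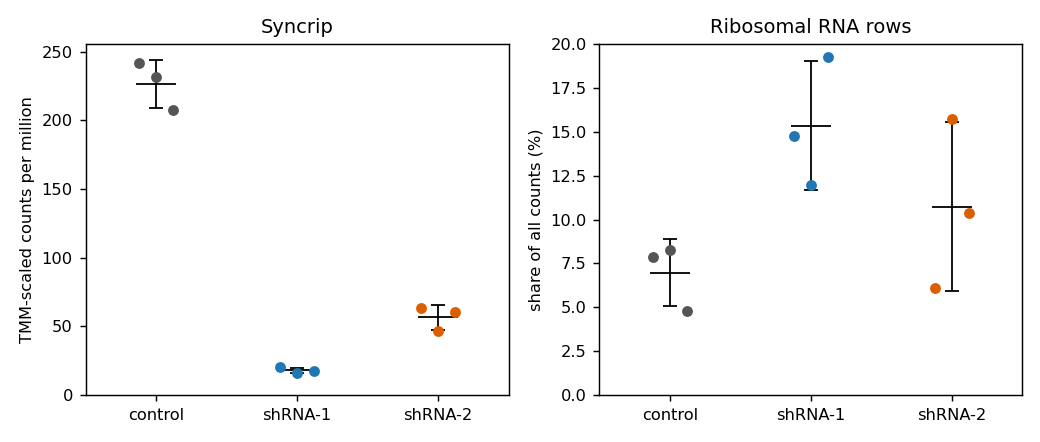
Left, TMM-scaled CPM of Syncrip in each library, and right, the share of all counts on the ribosomal RNA genes, for 3 control, 3 shRNA-1 and 3 shRNA-2 libraries. Points are libraries, lines are means and bars are SD. Syncrip lies at 227 ± 17.5 CPM in the controls and at 17.8 ± 2.13 and 56.7 ± 9.05 with the hairpins, and the ribosomal RNA share is highest with shRNA-1.

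With shRNA-1, genes known from neutrophils and their granules were among the largest rises. Mpo, which encodes the myeloperoxidase of primary granules (chromosome 11, 87793581 to 87804413), was 24.9-fold higher, at 526 ± 43.3 against 21.1 ± 6.17 CPM (log2 fold change 4.64 ± 0.29). Fpr1, a receptor for bacterial formyl peptides on neutrophils, rose by 3.54 ± 0.39. Anxa1, a phospholipid-binding protein that restrains inflammation, rose by 3.42 ± 0.23, Chi3l3, a chitinase-like protein of myeloid cells, by 3.402 ± 0.34, and Ppbp, a chemokine of platelets and monocytes, by 3.21 ± 0.62. After Syncrip, the largest falls were in Cep290, a centrosome and cilium protein (-2.87 ± 0.44), Elovl6, an elongase of fatty acids (-2.65 ± 0.34), the transcript RP24-312B12.1 (-2.53 ± 0.48) and Tpr, a protein of the nuclear pore basket (-2.50 ± 0.39). The 3 shRNA-1 libraries did not overlap the 3 controls for any of these genes, which was a condition of choosing them. Their adjusted p in edgeR's quasi-likelihood test ran from 8.26e-06 to 0.00260. Chi3l3 has close paralogs, so its reads are uncertain.

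The test called 4389 of 12663 genes with shRNA-1, 2201 higher and 2188 lower, and 1437 of the calls were changes of at least 2-fold. With the ribosomal RNA share as a covariate, a fit chosen after the data had been seen, 1358 genes were called, 1217 of them also called without it. The share is tied to this hairpin, so a call lost there does not show that ribosomal RNA made the change. Of 103 genes named by the rule and called with shRNA-1, 56 lost the call, and 42 of these kept at least 50% of their log2 fold change. The calls of Ppbp (adjusted p = 0.143) and RP24-312B12.1 (0.138) were lost there. Without control replicate 3 the calls numbered 2916, and without shRNA-1 replicate 2 they numbered 2925. Scaling to total counts alone moved the median of all tested genes to -0.23 with shRNA-1 and -0.21 with shRNA-2. Higher genes then made up 23.8% of 4549 calls with shRNA-1, against 50.1% with TMM. All changes are therefore relative to the bulk of the genes.

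With shRNA-2, genes known from macrophages were among the largest rises. C1qb, a chain of the complement starter C1q that macrophages secrete (chromosome 4, 136880129 to 136886187), went from 0.501 ± 0.376 CPM in the controls to 37.4 ± 26.6 (log2 fold change 6.31 ± 0.76), with 8.04, 59.9 and 44.3 CPM in the 3 shRNA-2 libraries. C1qc, another chain of it, rose by 5.78 ± 0.80. Bpifc, of the family of bacterial permeability proteins, rose by 5.24 ± 0.37, and Rgs5, a regulator of G-protein signalling, by 5.12 ± 0.52. The largest falls were in Abi2, a part of the WAVE complex that shapes actin (-3.80 ± 0.23), Chdh, a choline dehydrogenase (-3.69 ± 0.28), Cyp2a5, a cytochrome P450 enzyme (-3.09 ± 0.28), Angpt1, the ligand angiopoietin (-3.06 ± 0.24), and Ttc7b (-2.91 ± 0.17). The 3 shRNA-2 libraries did not overlap the 3 controls for these genes, a condition of choosing them. Their adjusted p in edgeR's quasi-likelihood test ran from 7.45e-07 to 0.000127.

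The test called 6162 of 12663 genes with shRNA-2, 3095 higher and 3067 lower. Of the calls, 2578 were changes of at least 2-fold, 1573 higher and 1005 lower. With total-count scaling, higher genes made up 33.6% of 6335 calls, against 50.2% with TMM. With shRNA-1, C1qb and C1qc stood at 1.56 ± 1.01 and 1.82 ± 0.99 (adjusted p = 0.253 and 0.175 in the same test), and passed only when shRNA-2 replicate 1 was left out of the fit (0.0293 and 0.0343).

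Among the largest changes with both hairpins were rises of C-type lectin receptors and falls of genes of mitosis. Clec4a3, Clec4a1 and Clec4n, lectin receptors that myeloid cells carry, rose by 2.82, 2.14 and 2.32 with shRNA-1 and by 3.91, 4.09 and 3.35 with shRNA-2 (log2 fold changes). Clec4n was the most abundant of them, at 85.2 ± 9.98 CPM in the controls, 425 ± 150.3 with shRNA-1 and 868 ± 189 with shRNA-2. The other large rises were in Ppbp, Anxa1, Chi3l3, the protease inhibitor Serpinb2, the matrix protein Tgfbi, Ptplad2, the nucleotide receptor P2ry13 and the lectin-like receptor Klra2, from 1.75 to 3.42 with shRNA-1 and from 2.13 to 4.34 with shRNA-2. Clec4a1, Clec4a3, Chi3l3 and Klra2 belong to families of close paralogs, so their reads are uncertain.

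Among the falls with both hairpins, Cenpe and Cenpf, motor and scaffold of the kinetochore, changed by -2.49 ± 0.38 and -2.34 ± 0.41 with shRNA-1 and by -1.80 ± 0.36 and -1.54 ± 0.39 with shRNA-2, and the mitotic motor Kif15 by -1.33 ± 0.25 and -2.57 ± 0.26. Kmt2a (chromosome 9, 44803355 to 44881296), the histone methyltransferase whose first part is in the MLL-AF9 fusion, went from 144 ± 29.6 CPM to 33.4 ± 2.63 and 32.7 ± 7.23, and how many of its reads come from the fusion is not known. Gata2, a transcription factor of blood stem and progenitor cells, fell by 2.38 and by 1.67, and Angpt1, which stem cells also express, by 2.03 and by 3.06. Cep290, the chaperone Hspa2, the RNA-binding protein Sltm, Chdh and the adhesion receptor Eltd1 made up the rest of the largest falls, with Hspa2 at -2.47 ± 0.18 and -2.58 ± 0.18. For all of these rises and falls the 6 knockdown libraries lay on 1 side of the 3 controls, a condition of choosing them. Adjusted p in edgeR's quasi-likelihood test ran from 9.06e-06 to 0.0304 with shRNA-1 and from 5.69e-07 to 0.00616 with shRNA-2.

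In all, 2382 genes were called with both hairpins in the same direction, 1170 higher and 1212 lower. At least 2-fold changes with both numbered 622, and 62.1% of these were higher. Of all 12663 genes, 3450 (27.2%) had the 6 knockdown libraries on 1 side of the 3 controls, where chance gives 2.38%. With total-count scaling 21.5% of 2700 such genes were higher, against 49.1% with TMM. The number was 1558 without control replicate 3 and 835 with the ribosomal RNA share as a covariate, 699 of them among the 2382. That covariate ended the shRNA-1 calls of Ppbp, Clec4a1, Serpinb2, Tgfbi, Ptplad2, Gata2, Kif15 and Cenpf (adjusted p from 0.0526 to 0.654), and their shRNA-2 calls held. With shRNA-1, Serpinb2 was lost without shRNA-1 replicate 2, shRNA-1 replicate 3 or control replicate 1 (highest adjusted p = 0.0592), and Tgfbi without these or control replicate 3 (0.106).

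Of the genes fixed by name, Msi2, Hoxa9, Meis1 and Myb, known from self-renewal of this kind of leukaemia, were lower with both hairpins. Msi2, an RNA-binding protein of leukaemia stem cells (chromosome 11, 88339382 to 88718513), was at 30.3 ± 1.25 CPM in the controls, 15.5 ± 2.004 with shRNA-1 and 8.10 ± 0.522 with shRNA-2. Its log2 fold changes were -0.97 ± 0.13 and -1.90 ± 0.14 (edgeR quasi-likelihood adjusted p = 0.000431 and 1.92e-06). Hoxa9 (chromosome 6, 52223100 to 52231089), a homeobox gene that MLL fusions keep on, went from 399 ± 35.9 CPM to 272 ± 8.38 and 147 ± 7.03 (log2 fold change -0.55 ± 0.11 and -1.44 ± 0.12, adjusted p = 0.00362 and 3.57e-06 in that test). Its cofactor Meis1 fell by 0.37 and by 0.37 (edgeR adjusted p = 0.0248 and 0.0161), and the transcription factor Myb by 0.33 and by 0.49 (0.0440 and 0.00431). Cdkn1a, the cell cycle inhibitor p21 and a target of p53, rose by 1.01 ± 0.20 and 1.94 ± 0.21 (edgeR adjusted p = 0.00330 and 2.37e-05), from 264 ± 28.3 to 530.3 ± 164 and 1009 ± 123 CPM.

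Myc was higher with shRNA-1 (0.63 ± 0.23, edgeR adjusted p = 0.0489) and stood at -0.27 ± 0.23 with shRNA-2 (0.342), a difference of 0.90 ± 0.23 between the hairpins (adjusted p = 0.00806). Ikzf2, the transcription factor Helios, stood at 0.32 ± 0.23 with shRNA-1 (edgeR adjusted p = 0.292) and fell by 0.62 with shRNA-2 (0.0390). Hnrnpr, the paralog of Syncrip, stood at -0.28 ± 0.12 (edgeR adjusted p = 0.0953) and fell by 0.42 (0.0118). The shRNA-1 call of Myc was lost without any 1 of the 3 shRNA-1 or 3 control libraries (highest adjusted p = 0.166), and its shRNA-2 value passed without shRNA-2 replicate 1 (0.00685). Meis1 was lost with shRNA-1 without any 1 shRNA-1 library, control replicate 2 or control replicate 3 (highest 0.0821), and with shRNA-2 without shRNA-2 replicate 3, control replicate 2 or control replicate 3 (0.0672). Myb with shRNA-1 was lost without any 1 shRNA-1 or control library or shRNA-2 replicate 3 (0.140). Ikzf2 with shRNA-2 was lost without shRNA-1 replicate 2, shRNA-2 replicate 2, shRNA-2 replicate 3, control replicate 1 or control replicate 2 (0.142). The ribosomal RNA covariate ended the shRNA-1 calls of Hoxa9, Meis1, Myb and Cdkn1a (adjusted p from 0.121 to 0.454) and the shRNA-2 call of Ikzf2 (0.0863).

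**Figure D2:**
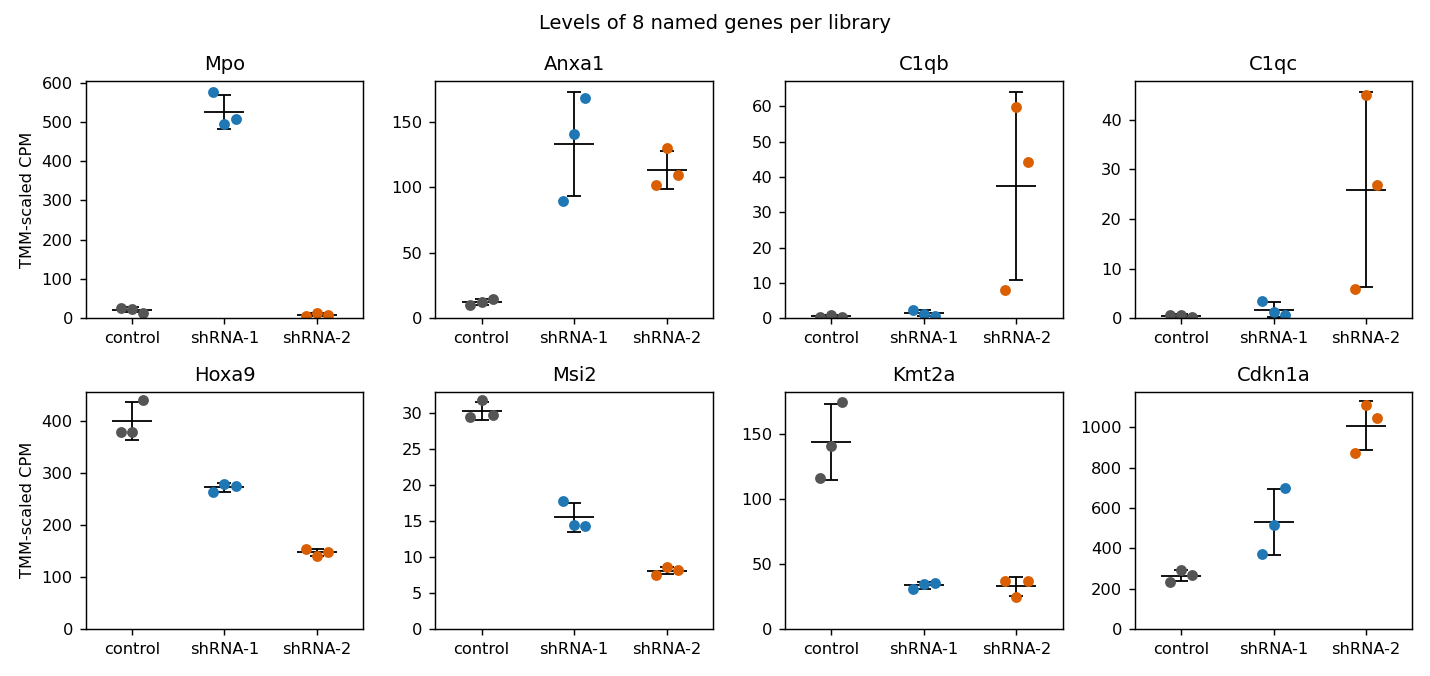
TMM-scaled CPM of 8 named genes in each library, 3 each of control, shRNA-1 and shRNA-2. Points are libraries, lines are means and bars are SD, and each panel has its own axis from 0. Mpo is high with shRNA-1 (526 ± 43.3), C1qb and C1qc with shRNA-2, Anxa1 and Cdkn1a with both, and Hoxa9, Msi2 and Kmt2a are lower with both.

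Gene lists set out how whole programmes moved, counted as members called with both hairpins and as camera tests against all other genes. Of all 12663 genes, 1170 rose and 1212 fell with both, and a count near these shares does not set a list apart. Among 24 genes of the MLL and HOX self-renewal programme, 12 fell and 1 rose with both hairpins, 14 and 1 adjusted over the list alone. The medians were -0.57 and -0.48 (camera adjusted p = 4.14e-06 and 0.00118 for shRNA-1 and shRNA-2, adjusted p = 0.173 and 0.327 with an estimated correlation). Hoxa3, of the same cluster as Hoxa9 (-2.43 ± 0.48 and -2.26 ± 0.45), and Jmjd1c, a demethylase family protein (-1.55 ± 0.22 and -1.57 ± 0.22), were its largest falls, and Cbx8, a Polycomb protein, its rise (0.74 ± 0.24 and 0.99 ± 0.24). Rises of MLL and HOX genes with both numbered 0 without shRNA-1 replicate 1, shRNA-1 replicate 2, control replicate 2 or control replicate 3, and the falls 5 with the ribosomal RNA covariate. Of 56 targets of MYC, 24 fell with both hairpins, 25 adjusted over the list alone (camera adjusted p = 9.07e-05 and 6.63e-10, adjusted p = 0.173 and 0.147 with an estimated correlation). They include the nucleolar proteins Tcof1 (-1.54 ± 0.29 and -1.04 ± 0.29) and Rrp12 (-1.40 ± 0.12 and -1.16 ± 0.12), and with the ribosomal RNA covariate the falls with both numbered 12. Of 42 hnRNP and MSI2-associated RNA-binding proteins, 10 fell, Syncrip and Msi2 among them, and Ptbp3 rose (1.16 ± 0.13 and 1.12 ± 0.13). The counts were 10 and 1 adjusted over the list alone, falls first (camera adjusted p = 0.0289 and 8.96e-05, adjusted p = 0.576 and 0.415 with an estimated correlation). Syncrip is the target of the hairpins, so its part in these counts and tests was fixed by the design. The list was not tested without it. Falls of hnRNP genes with both numbered 6 without shRNA-1 replicate 2, shRNA-1 replicate 3 or control replicate 2 and 2 with the ribosomal RNA covariate, and the rises 2 without control replicate 1. For shRNA-1 the hnRNP test was lost without shRNA-1 replicate 3 (camera adjusted p = 0.0813), without control replicate 1 (0.0916), without both outlying libraries (0.0620), with the trend in transcript length taken out (0.0776) and with the ribosomal RNA covariate (0.269). The shRNA-1 calls of Hoxa3 and Tcof1 were also lost with that covariate (edgeR adjusted p = 0.216 and 0.140), and that of Cbx8 without shRNA-1 replicate 1, shRNA-1 replicate 2, control replicate 2 or control replicate 3 (highest 0.137).

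Genes of mature myeloid cells were higher, neutrophil genes with both hairpins and monocyte genes above all with shRNA-2. Of 23 genes of mature neutrophils, 15 rose with both, 15 adjusted over the list alone, and 3 fell with shRNA-2. The rises were led by Anxa1 and Chi3l3. The list's medians were 1.51 and 1.11 (camera adjusted p = 6.62e-18 and 3.16e-05, adjusted p = 0.173 and 0.415 with an estimated correlation), and with the ribosomal RNA covariate the rises with both numbered 9. Of 33 genes of monocytes and macrophages, 15 rose with shRNA-1 and 30 with shRNA-2, 15 with both and 17 adjusted over the list alone. That list had medians of 0.93 and 2.13 (camera adjusted p = 5.21e-05 and 9.07e-18, adjusted p = 0.4998 and 0.203 with an estimated correlation), and with the covariate 4 rose with shRNA-1, all of them with both, at a median of 0.32. Mpeg1, a pore-forming protein of macrophages, rose by 2.09 ± 0.35 and 2.73 ± 0.35, and Fcgr4, an antibody receptor, by 1.00 ± 0.28 and 3.56 ± 0.29. Of 17 primary granule and progenitor genes, 1 rose with both hairpins and 3 fell, the same numbers adjusted over the list alone. With shRNA-1 5 rose and 5 fell, with shRNA-2 3 rose and 8 fell, and 3 were called in opposite directions. Elane, the elastase of primary granules, rose by 1.37 ± 0.27 and 1.20 ± 0.27. Cd34, a surface protein of progenitors, fell by 2.35 and by 0.49, and the receptor Csf3r by 1.11 and by 1.16. The list as a whole did not pass (camera adjusted p = 0.901 and 0.168), and its median with shRNA-1 (-0.13) had the other sign than its mean (0.20) and test. Falls of granule and progenitor genes with both numbered 1 without control replicate 3 and 1 with the ribosomal RNA covariate, the rises 2 without shRNA-2 replicate 1 and 0 with the ribosomal RNA covariate, and the median with shRNA-1 was -0.06 without control replicate 1 and -0.03 without shRNA-1 replicate 1. Several of these single calls rest on few libraries. Fcgr4 with shRNA-1 was lost without shRNA-1 replicate 3 or control replicate 1 (highest edgeR adjusted p = 0.0804), and Csf3r without shRNA-1 replicate 1, shRNA-1 replicate 2 or control replicate 3 (0.126). With shRNA-2, Csf3r was lost without shRNA-2 replicate 3 or control replicate 3 (0.0763) and Cd34 without control replicate 2 or control replicate 3 (0.0598). With the ribosomal RNA covariate the shRNA-1 calls of Elane, Mpeg1, Fcgr4 and Csf3r ended (edgeR adjusted p from 0.0669 to 0.514), as did that of Csf3r with shRNA-2 (0.0552). The primary granule list passed with shRNA-2 in that fit (camera adjusted p = 0.0368).

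Markers of other cell types found in mice moved in different directions. Of 6 megakaryocyte genes, 2 rose with both hairpins (2 adjusted over the list alone), Ppbp and the tetraspanin Cd9 (0.80 ± 0.17 and 2.26 ± 0.18). With shRNA-2 4 rose and with shRNA-1 1 fell (camera adjusted p = 0.672 and 0.00217, adjusted p = 0.173 for shRNA-2 with an estimated correlation), and the falls with shRNA-1 numbered 0 without control replicate 3 and 2 without shRNA-1 replicate 2 or control replicate 1. Without shRNA-1 replicate 2 the rerun filter kept 8 megakaryocyte genes, not 6. The summed level of that list was 48.3 ± 7.63, 88.8 ± 20.7 and 258 ± 6.30 CPM in control, shRNA-1 and shRNA-2. Of 4 erythroid genes 1, the most abundant, rose with shRNA-1 and 1 fell with both (camera adjusted p = 0.839 and 0.668). The summed erythroid level was 261 ± 10.8, 425 ± 35.4 and 242 ± 15.6 CPM, and the falls with both numbered 0 without shRNA-1 replicate 1, shRNA-1 replicate 2, shRNA-2 replicate 2, shRNA-2 replicate 3, control replicate 1 or control replicate 3 and 0 with the ribosomal RNA covariate. The summed levels in the same order were 197 ± 14.9, 117 ± 22.9 and 169 ± 20.7 for dendritic cells, 65.1 ± 22.5, 24.2 ± 13.7 and 15.1 ± 3.13 for eosinophils, and 49.2 ± 5.86, 42.4 ± 8.24 and 23.5 ± 4.95 for mast cells and basophils. They were 58.2 ± 7.54, 42.9 ± 2.08 and 82.5 ± 11.9 for stroma and endothelium, 40.5 ± 5.05, 27.1 ± 1.75 and 69.4 ± 7.91 for T and NK cells, and 18.8 ± 2.04, 16.7 ± 1.88 and 19.6 ± 3.34 for B cells (mean ± SD, n = 3 each).

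Of 4 eosinophil genes, Prg3 and Epx, proteins of the eosinophil granule, were among the 3 that fell with both, and 1 rose (the same numbers adjusted over the list alone, camera adjusted p = 0.0539 and 0.0657). Eosinophil genes that rose with both numbered 0 without shRNA-1 replicate 2, control replicate 1 or control replicate 2 and 0 with the ribosomal RNA covariate, and the falls 1 with the ribosomal RNA covariate. The eosinophil test passed with shRNA-1 without shRNA-1 replicate 2, shRNA-2 replicate 3, control replicate 1 or control replicate 2 (lowest camera adjusted p = 0.00470), and with shRNA-2 without shRNA-1 replicate 1, shRNA-1 replicate 2, control replicate 1 or control replicate 2 (0.0178). With the trend in transcript length taken out it passed with shRNA-1 (camera adjusted p = 0.0293). Gata2 was the 1 of 6 mast cell and basophil genes that fell with both, and 4 fell and 1 rose with shRNA-2 (camera adjusted p = 0.585 and 0.166). Mast cell genes that fell with both numbered 2 without shRNA-1 replicate 3, and the rises with shRNA-2 0 without shRNA-2 replicate 2, shRNA-2 replicate 3 or any 1 control. Of 5 dendritic cell genes Irf4 rose and Tcf4 fell with both, and 2 fell with shRNA-1 (camera adjusted p = 0.234 and 0.438). Rises of dendritic cell genes with shRNA-1 numbered 2 without shRNA-1 replicate 1, and with shRNA-2 2 without shRNA-1 replicate 2, shRNA-1 replicate 3, shRNA-2 replicate 1 or control replicate 3 and 3 without shRNA-1 replicate 1. Pdgfrb was the 1 of 7 stromal and endothelial genes that fell with both, 4 rose and 1 fell with shRNA-2, and 1 rose and 2 fell with shRNA-1 (camera adjusted p = 0.331 and 0.331). The falls with both and with shRNA-2 each numbered 2 without control replicate 1, and the rises with shRNA-1 0 without shRNA-1 replicate 2, shRNA-1 replicate 3 or control replicate 3 and 2 without shRNA-1 replicate 1. Of 7 T and NK cell genes 3 rose and 1 fell with shRNA-2 and Bcl11b fell with shRNA-1 by 0.86 (camera adjusted p = 0.227 and 0.234). Falls of these genes with shRNA-1 numbered 0 without shRNA-1 replicate 1, control replicate 2 or control replicate 3 and 2 without shRNA-2 replicate 1 or control replicate 1, and with shRNA-2 2 without shRNA-2 replicate 1. Of 4 B cell genes Bank1 rose with shRNA-2 (camera adjusted p = 0.926 and 0.482), and the rises numbered 2 without any 1 shRNA-1 library, shRNA-2 replicate 1, control replicate 1 or control replicate 2 and 3 without control replicate 3. The filter was rerun in these fits, and without any 1 shRNA-1 library or shRNA-2 replicate 1 it kept 5 B cell genes, not 4. With the ribosomal RNA covariate the shRNA-1 calls of Epx, Gata2, Irf4, Pdgfrb, Ppbp and Bcl11b ended (edgeR adjusted p from 0.0677 to 0.871). The Bcl11b call was lost without shRNA-1 replicate 1, shRNA-1 replicate 3, control replicate 2 or control replicate 3 (highest edgeR adjusted p = 0.133).

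More genes of G2 and mitosis fell than rose with both hairpins, and more genes of DNA replication with shRNA-2. Of 37 genes of G2 and mitosis, 13 fell and 4 rose with shRNA-1 and 29 fell with shRNA-2, 11 with both and 13 adjusted over the list alone, Cenpe and Cenpf among them. The camera test passed for each (medians -0.19 and -0.63, camera adjusted p = 0.0288 and 2.89e-07, adjusted p = 0.668 and 0.415 with an estimated correlation). For shRNA-1 the list's call was lost without shRNA-1 replicate 3 (camera adjusted p = 0.0862) or control replicate 1 (0.0571), with the filter at 5 CPM (0.0583) and with the ribosomal RNA covariate (0.913). The rises with shRNA-1 numbered 1 without shRNA-1 replicate 2, control replicate 2 or control replicate 3 and 2 without shRNA-1 replicate 1 or shRNA-1 replicate 3, and with the covariate the falls numbered 2 with shRNA-1 and 2 with both. Of 38 genes of DNA replication, 8 fell and 5 rose with shRNA-1, 23 fell and 1 rose with shRNA-2, and 7 fell with both (8 adjusted over the list alone). They include the helicase Blm (-0.88 ± 0.16 and -1.11 ± 0.16) and the origin factor Mcm10 (-0.65 ± 0.15 and -1.06 ± 0.15). Ccne1, the cyclin of entry into S phase, rose with both (0.81 ± 0.14 and 1.00 ± 0.14). The replication list passed with shRNA-2 alone (camera adjusted p = 0.901 and 5.21e-05, adjusted p = 0.327 for shRNA-2 with an estimated correlation), and with shRNA-1 its median, 0.07, had the other sign than its mean and test, and was 0.03 without shRNA-1 replicate 1, control replicate 2 or control replicate 3 and 0.04 without shRNA-1 replicate 3. Replication genes that fell with both numbered 3 without shRNA-1 replicate 2 or shRNA-1 replicate 3, 4 without control replicate 1 and 0 with the ribosomal RNA covariate. With shRNA-1 the falls numbered 3 without shRNA-1 replicate 2 or shRNA-1 replicate 3, 4 without control replicate 1, 5 without shRNA-1 replicate 1, control replicate 2 or control replicate 3 and 0 with the ribosomal RNA covariate, and the rises 3 without shRNA-1 replicate 2 or control replicate 3 and 2 with the ribosomal RNA covariate, so an excess of falls with that hairpin is not shown. The rises with shRNA-2 numbered 2 without shRNA-2 replicate 3.

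More targets of p53 rose than fell. Of 27 targets of p53, 12 rose and 1 fell with both hairpins, 12 and 2 adjusted over the list alone (camera adjusted p = 0.00414 and 0.00118, adjusted p = 0.4998 and 0.415 with an estimated correlation). Trp53inp1, which promotes cell death and autophagy, rose by 1.48 ± 0.32 and 2.55 ± 0.32, the RNA-binding protein Zmat3 by 1.02 ± 0.19 and 2.27 ± 0.19, and Fdxr, a mitochondrial reductase, fell (-0.82 ± 0.19 and -0.70 ± 0.19). Of 28 regulators of apoptosis, 9 rose with both (9 adjusted over the list alone), 16 rose and 3 fell with shRNA-2, and 3 fell with shRNA-1 (camera adjusted p = 0.228 and 0.00454, adjusted p = 0.173 for shRNA-2 with an estimated correlation). They include opponents, the killer Bcl2l11 (0.71 ± 0.14 and 1.87 ± 0.14) and the survival gene Bcl2a1b (0.72 ± 0.14 and 0.89 ± 0.14), whose paralogs make its reads uncertain. Apoptosis genes that rose with both numbered 5 without control replicate 1 and 5 with the ribosomal RNA covariate, and the falls with shRNA-1 1 without shRNA-1 replicate 1 and 5 without shRNA-2 replicate 1. The shRNA-1 calls of Cenpf, Blm, Mcm10, Trp53inp1, Zmat3 and Fdxr were lost with the ribosomal RNA covariate (edgeR adjusted p from 0.0526 to 0.306). The median of the p53 list with shRNA-1 was 0.52 without the covariate and 0.43 with it, while the members called higher went from 16 to 2 and those with both from 12 to 0, so the lost calls do not show that the rise was due to ribosomal RNA.

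Interferon-induced genes were higher with shRNA-2. Of 35 genes of the type I interferon response, 30 rose with shRNA-2, 9 rose and 2 fell with shRNA-1, 9 with both and 9 adjusted over the list alone. The medians were 0.44 and 1.92 (camera adjusted p = 0.112 and 4.65e-13, adjusted p = 0.404 for shRNA-2 with an estimated correlation). With shRNA-1 the rises, all of them also called with shRNA-2, numbered 4 without shRNA-1 replicate 3, 5 without control replicate 2 or control replicate 3, 20 without shRNA-1 replicate 1 and 2 with the ribosomal RNA covariate. The falls with shRNA-1 numbered 0 without control replicate 3, 1 without shRNA-1 replicate 1, shRNA-1 replicate 2, shRNA-2 replicate 3 or control replicate 2, 4 without shRNA-1 replicate 3 and 0 with the ribosomal RNA covariate, and the median was 0.14 without shRNA-1 replicate 3, 0.72 without shRNA-1 replicate 1 and 0.27 with the ribosomal RNA covariate. The test with shRNA-1 passed without shRNA-1 replicate 1 (camera adjusted p = 4.31e-05) and with total-count scaling (0.0316). What the list did with shRNA-1 therefore depends on single libraries. Oasl2, related to the sensors of double-stranded RNA, rose by 1.12 ± 0.27 and 4.13 ± 0.26, and the antiviral Ifit3 by 1.59 ± 0.42 and 3.71 ± 0.39. Ifit3 with shRNA-1 was lost without shRNA-1 replicate 3 (edgeR adjusted p = 0.0647), and the ribosomal RNA covariate ended the shRNA-1 calls of Ifit3 and Oasl2 as well as Fos, Cxcl3, Ccl2 and H2-T22, which follow (edgeR adjusted p from 0.0608 to 0.113).

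Of 26 genes of the NF-kappaB response, 5 rose with both (5 adjusted over the list alone), among them the chemokines Cxcl3 and Ccl2 (camera adjusted p = 0.402 and 0.0146, adjusted p = 0.668 for shRNA-2 with an estimated correlation). Those with both numbered 2 without shRNA-1 replicate 2, shRNA-1 replicate 3 or control replicate 2, 3 without control replicate 1 and 1 with the ribosomal RNA covariate. The NF-kappaB test passed with shRNA-1 without shRNA-1 replicate 1 (camera adjusted p = 0.0107) and was lost with shRNA-2 without control replicate 1 (0.0680). Of 17 immediate early genes, 5 rose with both (5 adjusted over the list alone, camera adjusted p = 0.0115 and 0.000219, adjusted p = 0.4998 and 0.374 with an estimated correlation), led by the transcription factors Klf6 (1.5005 ± 0.13 and 2.04 ± 0.13) and Fos (1.76 ± 0.36 and 1.57 ± 0.36). Without control replicate 1 that list was lost with shRNA-1 (camera adjusted p = 0.0760). Of 15 genes of MHC class I presentation, 2 rose with both (2 adjusted over the list alone), H2-T23 and H2-T22, and 11 with shRNA-2 (camera adjusted p = 0.925 and 0.000155, adjusted p = 0.173 for shRNA-2 with an estimated correlation). Of 9 genes of MHC class II presentation, 6 rose with shRNA-2 (camera adjusted p = 0.889 and 0.00393, adjusted p = 0.415 for shRNA-2 with an estimated correlation), and H2-DMb1, among the most abundant, stood at 0.31 ± 0.14 and 0.90 ± 0.14. With shRNA-1 the median of that list, -0.11, had the other sign than its test, and was -0.23 without shRNA-1 replicate 2, -0.16 without shRNA-1 replicate 1, -0.02 without shRNA-1 replicate 3 and -0.33 with the ribosomal RNA covariate.

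Lists of stress programmes moved in different directions. Targets of ATF4, which raise amino acid supply, were lower: 9 of 33 fell with both hairpins, 9 adjusted over the list alone (camera adjusted p = 0.0289 and 0.000350, adjusted p = 0.530 and 0.378 with an estimated correlation). ATF4 targets that fell with both numbered 4 without shRNA-1 replicate 2 or shRNA-1 replicate 3, 5 without control replicate 2 and 1 with the ribosomal RNA covariate. Among the 9 was the tRNA synthetase Eprs (-1.37 ± 0.21 and -1.08 ± 0.21). Of 19 genes of the cytosolic heat shock response, 7 fell with both, 7 adjusted over the list alone (camera adjusted p = 0.0192 and 0.00393, adjusted p = 0.530 and 0.480 with an estimated correlation). They include the cochaperone Stip1 (-1.06 ± 0.13 and -1.03 ± 0.13) and the chaperone Hsp90aa1 (-1.03 ± 0.24 and -0.86 ± 0.24). Of the heat shock genes, 1 fell with both with the ribosomal RNA covariate, and the median with shRNA-1, -0.20 with all libraries, was -0.46 without shRNA-1 replicate 2. Genes of the unfolded protein response were higher with shRNA-2, and 8 of 27 rose with both, 9 adjusted over the list alone (camera adjusted p = 0.129 and 0.0327, adjusted p = 0.480 for shRNA-2 with an estimated correlation). Derl3 and Edem1, which remove misfolded proteins from the endoplasmic reticulum, rose by 1.94 ± 0.36 and 1.01 ± 0.16 with shRNA-1 and by 3.57 ± 0.32 and 1.54 ± 0.16 with shRNA-2, and with the covariate 4 members rose with both. Of 22 genes of cholesterol synthesis 3 fell with both (2 adjusted over the list alone), Lss the most (camera adjusted p = 0.121 and 0.00414, adjusted p = 0.576 for shRNA-2 with an estimated correlation). Cholesterol genes that fell with both numbered 1 without any 1 shRNA-1 library or any 1 control, 5 without shRNA-2 replicate 2, 8 without shRNA-2 replicate 1 and 0 with the ribosomal RNA covariate. Of 28 genes of glycolysis and hypoxia 1 fell with both (camera adjusted p = 0.199 and 0.518), and the falls numbered 0 without control replicate 3, 2 without control replicate 1 and 0 with the ribosomal RNA covariate. The rises with both, 0 with all libraries, numbered 1 without shRNA-1 replicate 3, 2 without shRNA-2 replicate 1 and 2 with the ribosomal RNA covariate. With shRNA-1, the ATF4 list was lost without shRNA-1 replicate 3 (camera adjusted p = 0.105), without both outlying libraries (0.111) and with the filter at 5 CPM (0.138), and the heat shock list without control replicate 1 (0.0585). Both were lost with the ribosomal RNA covariate (camera adjusted p = 0.199 and 0.243), where the ATF4 median went from -0.32 to -0.20 and the heat shock median from -0.20 to -0.17. Hsp90aa1 and Lss were lost there too (edgeR adjusted p = 0.333 and 0.0909). The unfolded protein response with shRNA-2 was lost without shRNA-2 replicate 1 (camera adjusted p = 0.0781) or control replicate 3 (0.0645), with total-count scaling (0.0587), with the filter at 5 CPM (0.0693) and without both outlying libraries (0.0956).

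Among genes of the cell's basic machinery, lysosome and adhesion genes were higher with shRNA-2 and splicing factors lower. Of 36 lysosome and autophagy genes, 24 rose and 3 fell with shRNA-2, and 9 rose and 7 fell with shRNA-1. With both hairpins 7 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.668 and 7.64e-05, adjusted p = 0.404 for shRNA-2 with an estimated correlation). Lysosome genes that rose with both numbered 2 without shRNA-1 replicate 2, control replicate 2 or control replicate 3, 3 without shRNA-1 replicate 3 and 0 with the ribosomal RNA covariate, and the falls 0 without any 1 shRNA-1 library, control replicate 2 or control replicate 3 and 0 with the ribosomal RNA covariate. With shRNA-1 the rises numbered 4 without shRNA-1 replicate 2, control replicate 2 or control replicate 3, 5 without shRNA-1 replicate 3 and 0 with the ribosomal RNA covariate, and the falls 3 without control replicate 2, 4 without shRNA-1 replicate 1, shRNA-1 replicate 2 or control replicate 3 and 3 with the ribosomal RNA covariate. Of 22 genes of adhesion and migration, 14 rose and 2 fell with shRNA-2, and 8 rose and 5 fell with shRNA-1. With both 7 rose and Itga4 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 0.277 and 4.14e-06, adjusted p = 0.173 for shRNA-2 with an estimated correlation). Itga4, an integrin, changed by -0.88 ± 0.14 and -1.36 ± 0.14. The falls with shRNA-1 numbered 3 without control replicate 3, and with the covariate 3 rose and 2 fell with both. Of 36 splicing factors 5 fell with both, among them Srsf11 (-0.82 ± 0.14 and -0.72 ± 0.14, 5 adjusted over the list alone, camera adjusted p = 0.385 and 0.00138, adjusted p = 0.173 for shRNA-2 with an estimated correlation). Splicing factors that fell with both numbered 2 without control replicate 2 and 0 with the ribosomal RNA covariate, and the rises, 0 with all libraries, 1 without any 1 shRNA-2 library or control replicate 1 and 2 with the ribosomal RNA covariate.

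Of 64 nuclear genes of oxidative phosphorylation, 12 rose and 1 fell with both, the same numbers adjusted over the list alone (camera adjusted p = 0.00258 and 0.296, adjusted p = 0.648 for shRNA-1 with an estimated correlation). Ndufa1 and Atp5j, subunits of complex I and of ATP synthase, had the largest rises. Oxidative phosphorylation genes that rose with both numbered 8 without shRNA-1 replicate 2, 5 without control replicate 3 and 5 with the ribosomal RNA covariate, and the falls 0 without shRNA-1 replicate 1, shRNA-1 replicate 2 or control replicate 3. Of 78 genes of ribosomal proteins, 7 rose and 1 fell with both, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0143 and 0.839, adjusted p = 0.550 for shRNA-1 with an estimated correlation). Ribosomal protein genes that rose with both numbered 1 without control replicate 1, 2 without control replicate 3 and 4 without shRNA-1 replicate 1 or shRNA-1 replicate 2, and the falls 0 without any 1 shRNA-1 library, shRNA-2 replicate 3 or any 1 control and 0 with the ribosomal RNA covariate. Pseudogenes make the reads of these genes uncertain. Of 31 proteasome genes 4 rose and Psmc1 fell with both, the same numbers adjusted over the list alone (camera adjusted p = 0.162 and 0.410), and the rises numbered 0 without shRNA-2 replicate 2 or control replicate 3, 2 without shRNA-1 replicate 2, shRNA-1 replicate 3 or shRNA-2 replicate 3 and 0 with the ribosomal RNA covariate. The shRNA-1 calls of the oxidative phosphorylation and ribosomal protein lists were lost with the ribosomal RNA covariate (camera adjusted p = 0.736 and 0.378) and with the trend in transcript length taken out (0.578 and 0.840), and that of Srsf11 with the covariate (edgeR adjusted p = 0.0660). The ribosomal protein list was also lost without control replicate 1 (camera adjusted p = 0.05005).

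Of 21 histone genes and nuclear long RNAs, most of which lack a poly(A) tail or stay in the nucleus, 8 rose with shRNA-1, 2 rose and 5 fell with shRNA-2, and 1 rose with both, 1 adjusted over the list alone (camera adjusted p = 0.00414 and 0.438, adjusted p = 0.576 for shRNA-1 with an estimated correlation). With the ribosomal RNA covariate that shRNA-1 call was lost (camera adjusted p = 0.805). The rises with shRNA-1 numbered 3 without shRNA-1 replicate 3, 4 without control replicate 3 and 1 with the ribosomal RNA covariate, and those with both 0 without shRNA-1 replicate 2, shRNA-1 replicate 3, control replicate 1 or control replicate 2, 3 without shRNA-2 replicate 1 and 0 with the ribosomal RNA covariate. The falls with shRNA-2 numbered 3 without shRNA-2 replicate 1, shRNA-2 replicate 3 or control replicate 2 and 9 with the ribosomal RNA covariate. Of 8 mRNAs encoded by the mitochondrial genome 3 rose and 1 fell with shRNA-1 and 2 fell with shRNA-2 (camera adjusted p = 0.167 and 0.710). Falls of these mRNAs with shRNA-1 numbered 0 without any 1 shRNA-1 library, shRNA-2 replicate 3, control replicate 1 or control replicate 3 and 0 with the ribosomal RNA covariate, and with shRNA-2 1 without shRNA-1 replicate 2, shRNA-2 replicate 2, shRNA-2 replicate 3 or control replicate 3, 4 without shRNA-2 replicate 1 and 1 with the ribosomal RNA covariate. The most abundant, mt-Nd4, fell by 0.77 with shRNA-1 and stood at -0.40 ± 0.27 with shRNA-2. The shRNA-1 call of mt-Nd4 was lost without any 1 shRNA-1 library, shRNA-2 replicate 3, control replicate 1 or control replicate 3 (highest edgeR adjusted p = 0.231), and it passed with shRNA-2 without shRNA-2 replicate 1 (0.0214).

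**Figure D3:**
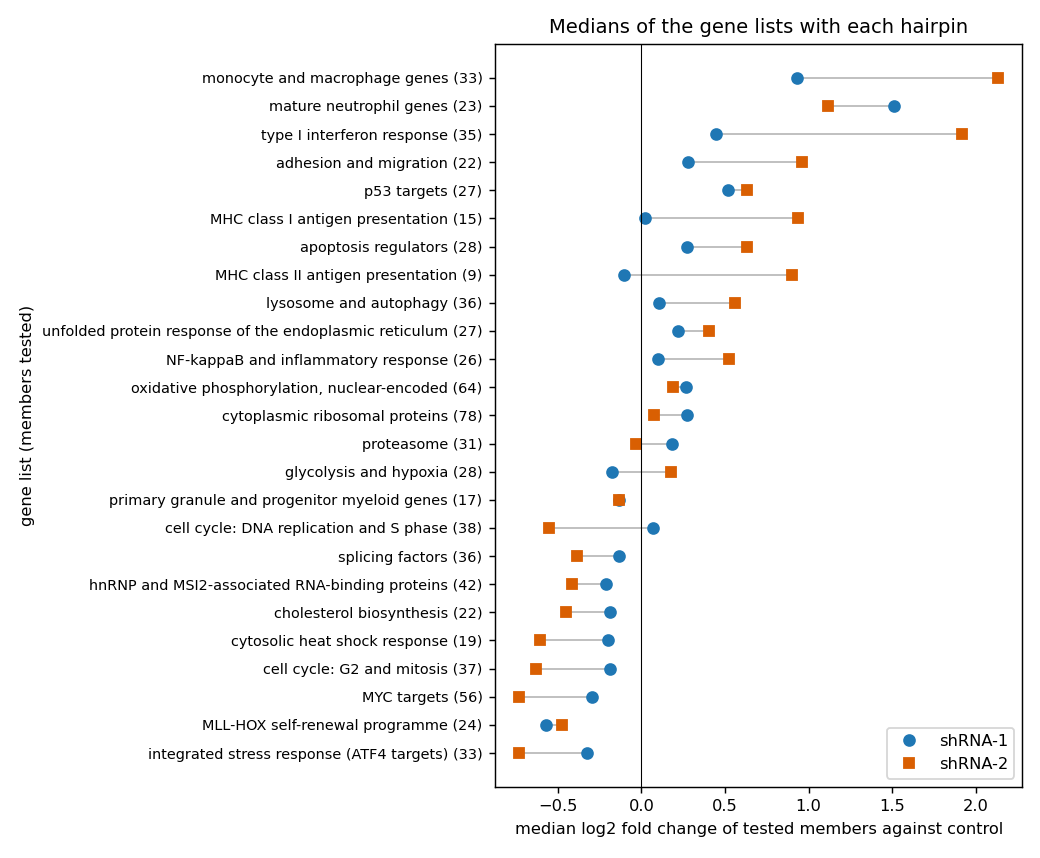
Median log2 fold change against control of the tested members of 25 gene lists of cell programmes, circles for shRNA-1 and squares for shRNA-2, with the number of members tested in brackets. The monocyte and macrophage list lies at 0.93 and 2.13, the interferon list at 0.44 and 1.92, and the list of the MLL and HOX programme at -0.57 and -0.48.

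Set against each other, the hairpins differed most in Mpo, higher with shRNA-1, and in Rgs5 and C1qb, higher with shRNA-2. Mpo was higher with shRNA-1 than with shRNA-2 by 5.94 ± 0.31 on the log2 scale, and fell with shRNA-2 against the control (-1.30 ± 0.27). Abi2 (4.28 ± 0.23), the RNA of ribonuclease P, Rpph1 (3.85 ± 0.33), the RNA-binding protein Rbpms2 (3.75 ± 0.22) and the microRNA gene Mir1949 (3.56 ± 0.38) were the other genes with the largest excess with shRNA-1. Rpph1 and Mir1949 are small RNAs without a usual poly(A) tail, so their counts are uncertain. Rgs5 (-4.79 ± 0.54), C1qb (-4.75 ± 0.70), Bpifc (-4.48 ± 0.36), the carbonic anhydrase Car4 (-4.41 ± 0.30) and the interferon-induced GTPase Gbp4 (-4.26 ± 0.30) were those with the largest excess with shRNA-2. The libraries of the hairpins did not overlap for these genes, a condition of choosing them. Adjusted p ran from 7.36e-07 to 0.000286 in edgeR's quasi-likelihood test. The test called 5192 of 12663 genes between the hairpins, 2499 higher with shRNA-1 and 2693 lower. Against the control, Abi2 passed with shRNA-1 as a rise (0.48 ± 0.17, edgeR adjusted p = 0.0498), which was lost without any 1 of the 3 shRNA-1 or 3 control libraries (highest 0.154). Mir1949 stood at 0.82 ± 0.30 (edgeR adjusted p = 0.0533) and passed without shRNA-1 replicate 1, shRNA-2 replicate 1 or shRNA-2 replicate 2 (lowest 0.0180).

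Across genes, which are not independent replicates, the fold changes of the hairpins went together in part. Hspa2, Kmt2a and Anxa1 had near equal values with both (-2.47 and -2.58, -2.10 and -2.13, 3.42 and 3.19), while Mpo and Rbpms2 were called in opposite directions. Hspa2, Kmt2a and Anxa1 were picked for large changes with both, and Mpo and Rbpms2 for differences between the hairpins. These examples therefore do not show how genes moved in general. Pearson's r over 12663 genes was 0.439, and 50 simulations of unchanged groups, with simulated controls shared by both hairpins, gave 0.453 ± 0.0127 (SD). The covariance was 0.292 against 0.0369 in the simulation, a difference of 0.255. The share of genes with the same sign was 67.7% against 65.9%. The simulated groups held no true changes, so noise of the shared controls set their r and same-sign share. Fold changes spread differently in the data, so r and this share cannot be judged against the simulated values. Independent lists of the same sizes would share 538 genes higher with both, 530 lower with both and 1068 in opposite directions, where the data held 1170, 1212 and 337. Of the 2382 genes called in the same direction, 701 also differed between the hairpins. The 3 controls cannot be split into parts of at least 2, so the excess was not tested free of the shared controls.

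**Figure D4:**
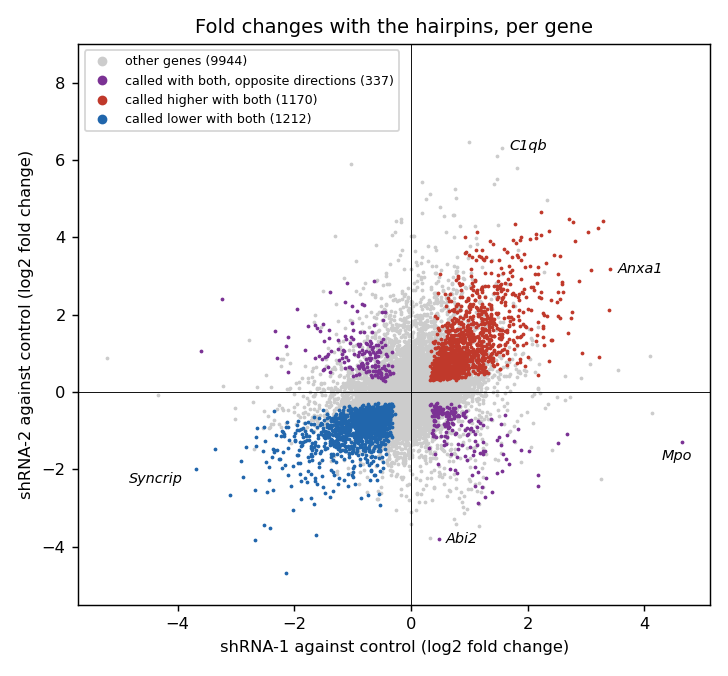
Log2 fold change of each of 12663 genes against control with shRNA-1 (x axis) and shRNA-2 (y axis). Red and blue points are the 1170 and 1212 genes called higher or lower with both hairpins, violet points the 337 called in opposite directions and grey points all others. Syncrip and Anxa1 lie among the genes that moved together, and Mpo and Abi2 among those that moved apart.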

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

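The values in this part stood out because a test of the difference itself separated the hairpins, and of the tests given here the one on the depth of the knockdown was chosen after the result was seen. Differences are shRNA-1 minus shRNA-2 on the log2 scale throughout, from edgeR's quasi-likelihood test for genes and from camera for lists.

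The hairpins differed in 5192 genes, and 337 genes were called with both in opposite directions. Among lists whose test passed, the monocyte and macrophage list had a median difference of -1.13, the interferon list -1.47, MHC class I -0.94, MHC class II -1.95, and adhesion -0.72. Also higher with shRNA-2 were the lists of lysosome -0.51, immediate early genes -0.54, apoptosis -0.29 and NF-kappaB -0.22. Marker lists higher with shRNA-2 were those of megakaryocytes (-1.60), T and NK cells (-1.37), stroma and endothelium (-1.19) and dendritic cells (-0.64). Lists higher with shRNA-1 were DNA replication (0.51), G2 and mitosis (0.45), ATF4 targets (0.51), MYC targets (0.35), hnRNP proteins (0.30), splicing factors (0.21), proteasome (0.21) and histones with nuclear RNAs (1.01). The neutrophil list passed toward shRNA-1 with a mean of 0.57, while its median, -0.00554, had the other sign. With an estimated correlation no list passed between the hairpins, where adjusted p ran from 0.151 to 0.564 for the lists named.

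Named genes higher with shRNA-2 than with shRNA-1 were the macrophage genes C1qb (-4.75), C1qc (-3.96) and Fcgr4 (-2.55), the interferon genes Gbp4 (-4.26), Oasl2 (-3.01) and Ifit3 (-2.12), and the lectins Clec4a1 (-1.95), Clec4a3 (-1.09) and Clec4n (-1.03). The same held for Rgs5 (-4.79), Bpifc (-4.48), Car4 (-4.41), Serpinb2 (-2.56), P2ry13 (-2.17), Ptplad2 (-2.12) and Tgfbi (-1.92). It held with smaller differences for Elovl6 (-1.70), Cd34 (-1.85), Syncrip (-1.68), Derl3 (-1.62) and RP24-312B12.1 (-1.61), and for Zmat3 (-1.25), Tpr (-1.24), Bcl2l11 (-1.16), Trp53inp1 (-1.07), Cdkn1a (-0.93), Klf6 (-0.54) and Edem1 (-0.53). List members higher with shRNA-2 were Irf4 (-1.68), Cd9 (-1.46), H2-T23 (-0.95), Ccl2 (-0.87), Bank1 (-0.79), H2-DMb1 (-0.59), Ndufa1 (-0.46) and Psmc1 (-0.42). Higher with shRNA-1 were Mpo (5.94), Abi2 (4.28), Rpph1 (3.85), Rbpms2 (3.75), Mir1949 (3.56), Cyp2a5 (3.08), Fpr1 (2.97), Ttc7b (2.37), and Chdh (2.07), followed by Eltd1 (1.33), Chi3l3 (1.27), Kif15 (1.24), Angpt1 (1.03), Ikzf2 (0.95), Msi2 (0.93), Myc (0.90), Hoxa9 (0.88), Itga4 (0.48) and Mcm10 (0.42). Calls between the hairpins were lost for Tgfbi without shRNA-1 replicate 1, shRNA-2 replicate 2 or shRNA-2 replicate 3 (highest edgeR adjusted p = 0.0648), for RP24-312B12.1 without shRNA-1 replicate 1, shRNA-1 replicate 2, shRNA-2 replicate 1 or shRNA-2 replicate 3 (0.0775), and for Tpr without shRNA-1 replicate 1, shRNA-1 replicate 3, shRNA-2 replicate 1 or shRNA-2 replicate 3 (0.0704). They were lost too for Trp53inp1 without shRNA-2 replicate 3 (0.0521), for Edem1 without shRNA-1 replicate 1, shRNA-1 replicate 2 or shRNA-2 replicate 2 (0.0760), and for Mcm10 without shRNA-1 replicate 1, shRNA-1 replicate 2, shRNA-2 replicate 2, shRNA-2 replicate 3 or any 1 control (0.164). Among list members the same was so for Bank1 without any 1 shRNA-1 library, shRNA-2 replicate 3, control replicate 1 or control replicate 2 (highest edgeR adjusted p = 0.175), Itga4 without shRNA-1 replicate 2, shRNA-1 replicate 3 or shRNA-2 replicate 2 (0.0645), Ndufa1 without shRNA-1 replicate 1 or shRNA-1 replicate 3 (0.0713), and Psmc1 without shRNA-1 replicate 1, shRNA-1 replicate 3 or shRNA-2 replicate 3 (0.0886).

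The interferon genes were weighed further because a response to the hairpin RNA itself would not be an effect of SYNCRIP. A deeper knockdown of Syncrip mRNA at day 4 with shRNA-2 is excluded as the cause, since Syncrip was lower with shRNA-1 (log2 difference -1.68). Protein and earlier times are not in these data, so a deeper loss of SYNCRIP protein with shRNA-2 stays open. A single aberrant shRNA-2 library is excluded too, since the list median between the hairpins was -1.47 with all libraries and came no closer to 0 than -1.35 when 1 shRNA-2 library was left out. A response to the shRNA-2 sequence or vector may be the source, and it cannot be told apart from an effect of SYNCRIP because the design holds 1 control hairpin group and no rescue. An off-target effect of shRNA-2 on other genes stays open and was not tested.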

How the results depend on the processing

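Fits with the ribosomal RNA genes left out, with the length or GC trend taken out, with the ribosomal RNA share as a covariate and without the 2 outlying libraries were chosen after the data had been seen. The fall of Syncrip passed its test under all alternatives run, from -3.92 to -3.54 with shRNA-1 and from -2.20 to -1.87 with shRNA-2, and r between the hairpins ran from 0.379 to 0.511. At an adjusted p under 0.01 the calls were 2300 with shRNA-1, 4263 with shRNA-2, 3318 between the hairpins and 1199 with both, and with at least 2-fold 1437, 2578, 2108 and 622, fewer by construction. With the ribosomal RNA covariate they were 1358, 5788, 4975 and 835, and the cause was not tested, since the covariate is partly tied to the groups. Leaving out 1 library gave 2916 to 5178 calls with shRNA-1, 5141 to 6432 with shRNA-2, 4028 to 5412 between the hairpins and 1558 to 2797 with both, in each case with fewer samples. Of all genes the rule named and called, 56 of 103 with shRNA-1 and 4 of 114 with shRNA-2 were lost with that covariate (median SE with shRNA-1 0.240 without and 0.283 with it), and 29 and 14 when some 1 library was left out. With the covariate mt-Nd4 and Bcl11b turned sign with shRNA-1, at 0.0572 and 0.0613, as did the test of the G2 and mitosis list with shRNA-1 (camera adjusted p = 0.913). Over all settings, 5269 other values of named genes kept direction and side of the threshold, 366 lost and 52 gained the call. Of the 366, 44 were lost at an adjusted p under 0.01 and 61 with at least 2-fold, where calls can only be lost. With the trend in transcript length taken out, 9 were lost. For list tests the numbers kept, lost and gained were 1211, 63 (35 of them with the estimated correlation) and 15. No called list turned direction under another scaling. No source ties libraries of equal replicate number. As a hint from the data, 6 of 9 libraries were closest to their own number, and deviations from group means correlated between equal numbers at -0.129 to 0.335, 7 of 9 above 0, with a mean as high in 2 of 36 assignments of the numbers (a count made after the data had been seen). With the replicate number as a block the calls were 4963, 6645, 5640 and 2780, the unfolded protein response with shRNA-2 had camera adjusted p = 0.0536, and the eosinophil list 0.0113 and 0.0184. At this depth and spread, simulated changes of 1.5-fold were mostly missed (20.4% recovered with shRNA-1). Few genes were changed in that simulation, which made its adjusted threshold stricter than in the data. The share missed in the data is not known.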

Other observations

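The scan of gene families, the relation of fold changes to transcript length and the tests per hairpin with the ribosomal RNA covariate were chosen after the data had been seen, and the other tests of this part were written before their results. A scan covered 176 families that share a name stem. In it, 7 of 17 tested C-type lectin genes (Clec) rose with both hairpins (medians 0.27 and 1.63, camera adjusted p = 0.00437 and 0.000584). The Anxa family (3 of 8 rose with both, camera adjusted p = 0.0451 and 0.00114) and the Serpinb family (3 of 8, 0.0494 and 0.0248) passed too. Of 8 matrix metalloproteinase genes (Mmp), 4 rose with both, but the family did not pass with shRNA-1 (medians 1.00 and 1.37, camera adjusted p = 0.0528 and 0.00548). Falls with both hairpins were seen in 7 of 10 Chd chromatin remodellers (-1.20 and -1.12, camera adjusted p = 2.43e-05 and 0.00703), 11 of 26 Kif kinesins (-0.65 and -0.80, 0.000482 and 0.00437), 13 of 30 Cep centrosome genes (-0.63 and -0.58, 0.00366 and 0.0146) and 13 of 34 Ddx RNA helicases (-0.27 and -0.55, 0.00580 and 0.00901). The Rrp family passed too, with 3 of 8 lower with both (-0.31 and -0.67, camera adjusted p = 0.0434 and 0.00580). The small nucleolar RNAs of the Snora family, 15 tested, had a median of 1.24 with shRNA-1 and -1.35 with shRNA-2 (camera adjusted p = 0.000982 and 0.0237), and the difference of the hairpins was not tested for this family. With an estimated correlation none of these families passed (adjusted p = 0.714 for Clec, 0.714 for Chd and 0.751 for Snora with shRNA-1). The scan was not repeated with the length trend taken out or with the ribosomal RNA covariate. How far these changes follow transcript length or library quality was therefore not tested.

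Long transcripts more often fell. Among 8859 genes in 5 classes of transcript length, 3.16% of the shortest and 20.4% of the longest fell with both hairpins, 15.7% and 5.93% rose, and the median log2 fold change went from 0.21 to -0.21 with shRNA-1 and from 0.18 to -0.20 with shRNA-2. A library quality that moves length and ribosomal RNA together may lie behind it, since across the 9 libraries deviations of the long-minus-short score and of the log2 ribosomal RNA share from their group means had r = -0.776 (exact permutation p within groups 0.0648, 216 permutations, two-sided, Spearman's rho -0.767 with p 0.0648, 1 relation computed), which fails the threshold and falls to r = -0.312 without the 2 libraries farthest from the median, so the relation rests on those. For the G2 and mitosis list, length is excluded as the whole cause, since 10 of 11 members called lower with both hairpins kept the call with the trend taken out (the larger list median was -0.23). With the ribosomal RNA covariate the list's larger median was 0.000702, but it lay at -0.19 before, already above the bound of -0.2 set for this test, so for both hairpins together the covariate cannot be told apart from the groups. Per hairpin, 2 of 13 called members kept the call with shRNA-1 (median -0.19 before and 0.00 after, median SE 0.173 and 0.207). Ribosomal RNA content may be a source of that fall, though the share is tied to this hairpin. With shRNA-2, 23 of 29 kept the call (median -0.59), which excludes the ribosomal RNA share as the whole source there.

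The rise of monocyte and macrophage genes was weighed against cells carried over from the mice and against library quality. The 33 monocyte genes lay above 28 pooled markers of other blood and stromal cells with both hairpins (medians 0.93 and -0.20 with shRNA-1 and 2.13 and 0.92 with shRNA-2, permutation p = 0.00034 and 0.00106, across genes), but pooling was too wide a test, since the megakaryocyte list alone had a median of 2.26 with shRNA-2 and the summed erythroid level was 425 ± 35.4 CPM with shRNA-1 against 261 ± 10.8 in the controls, so carry-over of blood cells stays open, normal monocytes included. A length trend is excluded as the whole source, since 15 of 15 members called with both hairpins kept the call with it taken out (the smaller list median was 0.91). The ribosomal RNA share is excluded as the whole source for shRNA-2, where 29 of 30 called members kept the call with the covariate (median 2.197). It cannot be told apart from the hairpin with shRNA-1, where 4 of 15 kept the call as the median went from 0.93 to 0.32 and the median SE from 0.287 to 0.404. Myeloid maturation after loss of SYNCRIP stays a hypothesis, to be tested with cells sorted for the leukaemia.

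Other splits of the libraries were fitted in the same way. For shRNA-1 against control (4389 calls), shRNA-2 against control (6162) and the hairpins against each other (5192), only 1 of the 10 splits of 6 libraries, the real one, gave as many calls and the highest other gave 0. These 10 splits are too few for a share under 0.05. For calls with both hairpins, 100 of the 840 partitions into 3 groups were fitted. Of these, 2 gave as many calls as the real 2382, the real one included, and the highest other gave 3320. That other partition held the same 3 groups with shRNA-2 in place of the control as the reference, so it is no chance regrouping. Among the partitions that mixed libraries of different groups 0 gave as many and the highest gave 2207. Of 99 other partitions 7 gave any call, and each of those kept the 3 libraries of 1 group together as the reference, with shRNA-2 in 4 of them. Such partitions are few among the 840, so a low share was to come for any groups that differ. The share therefore does not show that the hairpins have an effect in common.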
